A study of Homo sapiens with 12 samples.

How the data were processed

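RNA was measured in Huh7 cells, a human hepatoma line, carrying a doxycycline-inducible construct for A1CF, an RNA-binding cofactor of the apolipoprotein B mRNA editing enzyme. Per the labels, 1 clone carried wild-type (WT) A1CF and 1 carried the G398S form, and each was sampled with and without doxycycline. The labels list 12 libraries in 4 groups of 3, made from total RNA with a strand-specific kit that depletes ribosomal and globin RNA. The labels do not say whether the 3 libraries of a group came from separate cultures, so the authors' p-values may measure technical spread.

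The submitters' processing notes name bcl2fastq 2.9.1, STAR 2.5.0b, Cufflinks 2.2.1, Cuffdiff with no version, and the human genome build hg19. The settings of these tools, and whether strand was used in counting, are not given in the sources used here. The values analysed were 2 deposited tables, 1 for each clone, laid out as Cuffdiff gene tables and holding genes that the authors marked as significant. Group labels in 1 table carried a mutant prefix, and the other table was taken as WT from the name under which it was deposited. Per the file headers, each row gave 1 FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) for each group, so the deposited FPKM are the authors' pooled values and carry no replicate spread. Also per the file headers, each row gave a log2 fold change, which equalled the log2 ratio of the 2 group FPKM with no pseudocount, and a test statistic, a score of the authors' comparison. Deposited p-values came in steps of 5e-05, which was also the smallest value, and each had a q-value adjusted for the false discovery rate. Library depths are unknown, since the tables hold no counts, and no count or interval was inferred from them. Each table was normalised on its own, so levels set side by side across clones are descriptive. Gene starts were counted from 0 in the files, since end minus start equalled the annotated length of the transcript for 8 genes against 1 gene under the other reading. A value of 1 was added to each start.

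The number of genes tested was recovered from the deposited p-values and q-values, because an adjusted value is the p-value times the number tested divided by its rank. The smallest number that made every rank whole was 15109 for WT and 17072 for G398S. The next larger numbers to do so were 30218 and 34144, so the ranks and expected numbers below rest on taking the smallest. The ranks imply 172 genes past a q of 0.05 for WT, of which 142 were analysed here, and 2114 for G398S, of which 1863 were analysed here. A gene missing from these values was therefore not analysed here, and its absence says nothing about its change. For the same reason a count adjusted over the list alone cannot be given for any gene list, since p-values of members outside the tables were not analysed here.

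Before the data were examined, 29 gene lists with 710 distinct genes were fixed for liver lipid metabolism, hepatocyte functions, stress, inflammation, growth and other cell types. The direction of a list was tested with a two-sided Fisher exact test of higher against lower genes in the list against all other genes of the table, for lists with at least 3 genes. The number of list genes in a table was tested with a one-sided Fisher exact test against the number of genes tested. Every list member was taken as tested, which on its own makes the test conservative. The background held all tested genes whatever their expression, which favours a call for lists of well-expressed genes. Expected numbers for such lists may therefore be too low. Both families were adjusted over lists and tables with the Benjamini-Hochberg method. Genes in both tables were counted against the number expected from independent lists, with a hypergeometric test, and the share with the same sign with an exact binomial test. For these genes the difference of the 2 log2 fold changes was tested with a normal approximation, using the log2 fold change divided by the test statistic as its standard error. The plan made that test conditional on p-values close to the normal p of the statistic. The normal p was larger than the deposited one, by a median factor of 133 for WT and 50.6 for G398S, so the condition was not met. The test was run nonetheless and is conservative for a typical gene. It is not so for genes with large statistics at the smallest p-value. For HBG2, for example, the standard error of the difference was 0.72, against 2.10 from the p-values.

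The genes named with values were chosen by a rule fixed with the lists. It took genes past a q of 0.05 with both group values above 0, at least 1 FPKM in the higher group, a single symbol and no small RNA symbol. Of these it named the 10 largest rises and 10 largest falls in each table, up to 4 genes per list and table, A1CF, the 10 genes in both tables with the largest mean change, and up to 10 with opposite signs. It also named APOBEC1 and APOB, which were not analysed here. Other list members are named without values, and a gene chosen after its values were seen is marked as such. A few genes that the rule or the lists take are counted but not reported here by name.

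Other settings chosen at the same stage were a q of 0.01, an absolute log2 fold change of at least 1, at least 1 FPKM in the higher group, removal of genes at 0, removal of small RNA and several-gene rows, other numbers of genes tested, pseudocounts of 1 and 0.1 FPKM, and a standard error from the p-value. Alternatives added after the data were seen were removal of globin rows, matching on any symbol, Fisher exact tests of list directions between the tables, G398S statistics rescaled to the standard errors of WT, and directions shuffled within strata of GC content or transcript length. GC content and length came from the longest GENCODE release 29 transcript of each gene, matched by current or older symbol for 96.3% of the G398S genes and 98.6% of the WT genes. That annotation is on another genome build, so none of its coordinates were used. Strata were deciles (10) for G398S and quintiles (5) for WT, with 10000 permutations. Medians of GC content and length were compared with two-sided permutation tests of 100000 resamples. For neighbouring genes, the directions of consecutive G398S genes less than 100 kb apart on a chromosome were compared with shuffled directions in a one-sided permutation test, without globin rows and rows that repeat a gene.

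The scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. On simulated data with known answers, the number of genes tested was recovered in 10 of 10 runs for each table. The search there covered a narrow range around the true number, so those runs do not test the choice of the smallest number. A planted list of 14 genes moving 1 way was called in 100 of 100 runs on the 1863 G398S genes and in 82 of 100 runs on the 142 WT genes. Lists with no planted direction were called in 5 of 900 cases for G398S and 6 of 900 for WT. Simulated directions were drawn for each gene on its own, so these runs do not cover lists whose genes move together. The Fisher exact tests of lists also take genes as independent, so their p-values may be too small for such lists.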

Results

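Gene expression was compared with and without doxycycline in 2 Huh7 clones, 1 with inducible WT A1CF and 1 with inducible G398S A1CF, with 3 libraries per group. The study asked how the wild-type and mutant proteins differ in their effect on lipid metabolism of the cell. No group had doxycycline without a construct, and each construct was represented by 1 clone. Group FPKM are the authors' pooled values with no error attached, folds are ratios of these values, and the number of libraries behind each group is 3 throughout. Positions are on hg19.

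A1CF itself was higher with doxycycline in both clones. The gene (chromosome 10, 52559039 to 52645465 in the WT table) went from 19.5 to 33.2 FPKM in the WT clone and from 26.3 to 80.9 FPKM in the G398S clone. In the authors' deposited table for WT the log2 fold change was 0.76 (q = 0.00699), and in the authors' deposited table for G398S it was 1.62 (q = 0.00104). The rise was larger in the G398S clone by 0.86 on the log2 scale (95% interval 0.24 to 1.47), past the adjusted threshold of 0.05 over the 65 genes in both tables. With standard errors taken from the p-values, which bottom out at 5e-05, the interval was -0.01 to 1.72 and the difference was not called, so a larger rise in G398S is not settled. The values do not separate construct RNA from that of the resident gene.

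Induction of WT A1CF was accompanied by lower expression of inflammatory genes and higher expression of sterol synthesis genes. All 14 genes of the NF-kappaB and cytokine list in the table fell, among them the chemokines CXCL10, CXCL5 and CXCL8 and the apoptosis inhibitor BIRC3. All 8 genes of the cholesterol list in the table rose, including INSIG1, a sterol-regulated retention factor, and the enzymes MSMO1, IDI1 and FDFT1. All 5 genes of the ATF4 list in the table rose, among them ASNS, which makes asparagine, and STC2, TRIB3 and DDIT4, though their direction did not pass the test (Fisher exact test, adjusted p = 0.0529). SCD, the stearoyl-CoA desaturase, was 2.13-fold higher and the acute-phase gene SAA1 was 9.24-fold lower.

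In all, 142 genes of the WT comparison were analysed, 56 higher and 86 lower with doxycycline. At an absolute log2 fold change of at least 1 the balance shifted further to falls, with 9 higher and 42 lower, the latter including GP9, which was listed at 0 FPKM with doxycycline. The median absolute log2 fold change was 0.84.

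The NF-kappaB and cytokine list held the largest group. In the authors' deposited table CXCL10 had a log2 fold change of -2.46, CXCL5 of -1.97, BIRC3 of -1.88 and CXCL8 of -1.66, each with q = 0.00699. With 1 FPKM added to both groups these were -1.47, -1.93, -0.76 and -1.55, as BIRC3 and CXCL10 had low values. CXCL5 went from 97.5 to 24.9 FPKM and CXCL8 from 26.3 to 8.30 FPKM. The chemokines CXCL1 and CCL20 and the NF-kappaB inhibitor TNFAIP3 had log2 fold changes of -1.64, -1.31 and -0.93 in the authors' deposited table. That of TNFAIP3 shrank to -0.53 with 1 FPKM added. CXCL6, RELB, NFKB2, SOD2, TNFAIP2, NFKBIA and ICAM1 made up the rest. The 14 genes stood against 0.244 expected among 26 list members (adjusted p = 1.11e-20), and their direction differed from that of the other genes of the table (Fisher exact test, adjusted p = 0.0114). UBD, a ubiquitin-like modifier, fell from 58.5 to 12.6 FPKM, and IKBKE, a kinase of innate immune signalling, fell from 8.79 to 2.15 FPKM. The transcription factors EHF and BATF fell from 1.28 to 0.321 FPKM and from 2.91 to 0.733 FPKM, log2 fold changes that shrank to -0.79 and -1.17 with 1 FPKM added. VNN3, a vanin family gene, fell by 2.64 on the log2 scale in the authors' deposited table.

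Of the 27 members of the cholesterol list, 8 were in the WT table against 0.254 expected (adjusted p = 2.76e-09), all higher (Fisher exact test of direction, adjusted p = 0.0114). INSIG1 rose from 27.2 to 57.8 FPKM, MSMO1 from 129 to 217 FPKM, IDI1 from 71.6 to 106 FPKM and FDFT1 from 74.5 to 110.0 FPKM. DHCR7, CYP51A1 and HMGCS1 also rose. The fatty acid and triglyceride list had 3 genes in the table (Fisher exact test, adjusted p = 0.0103 for their number). SCD and ACSS2, which makes acetyl-CoA from acetate, rose with log2 fold changes of 1.09 and 0.87 in the authors' deposited table, while the acyl-CoA synthetase ACSL1 fell with -0.58. Their direction did not differ from that of the other genes (Fisher exact test, adjusted p = 0.759). LIPG, endothelial lipase, was the 1 gene of the lipoprotein list and rose 1.67-fold.

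The ATF4 list gave 5 genes against 0.263 expected (Fisher exact test, adjusted p = 0.000109), with the direction as given above. At a log2 fold change of at least 1 none of them was left (adjusted p = 1), and the number of cholesterol, fatty acid and acute phase genes was not called either (Fisher exact tests, adjusted p = 0.602, 0.602 and 0.683). STC2 and ASNS were 1.81-fold and 1.79-fold higher, TRIB3 1.72-fold and DDIT4 1.67-fold, and SLC7A11 was the fifth member. The acute phase and complement list gave 3 genes, all lower (Fisher exact test, adjusted p = 0.0248 for number and 0.470 for direction). Their number was no longer called at a q of 0.01 (Fisher exact test, adjusted p = 0.0806). SAA1 went from 7.42 to 0.803 FPKM, complement C3 from 48.4 to 26.6 FPKM and kininogen KNG1 from 99.0 to 70.0 FPKM. Of the hepatocyte list, TDO2, which starts tryptophan breakdown, and the vitamin D binding protein GC fell 2.93-fold and 1.70-fold. With 1 FPKM added the log2 fold change of TDO2 shrank from -1.55 to -0.95. IFITM3 of the interferon list fell, as did the lysozyme gene LYZ of the immune cell list, from 83.9 to 39.4 FPKM. FBN1 rose and MMP14 fell in the matrix list. The other 19 of the 29 lists had no gene in the table.

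**Figure D1:**
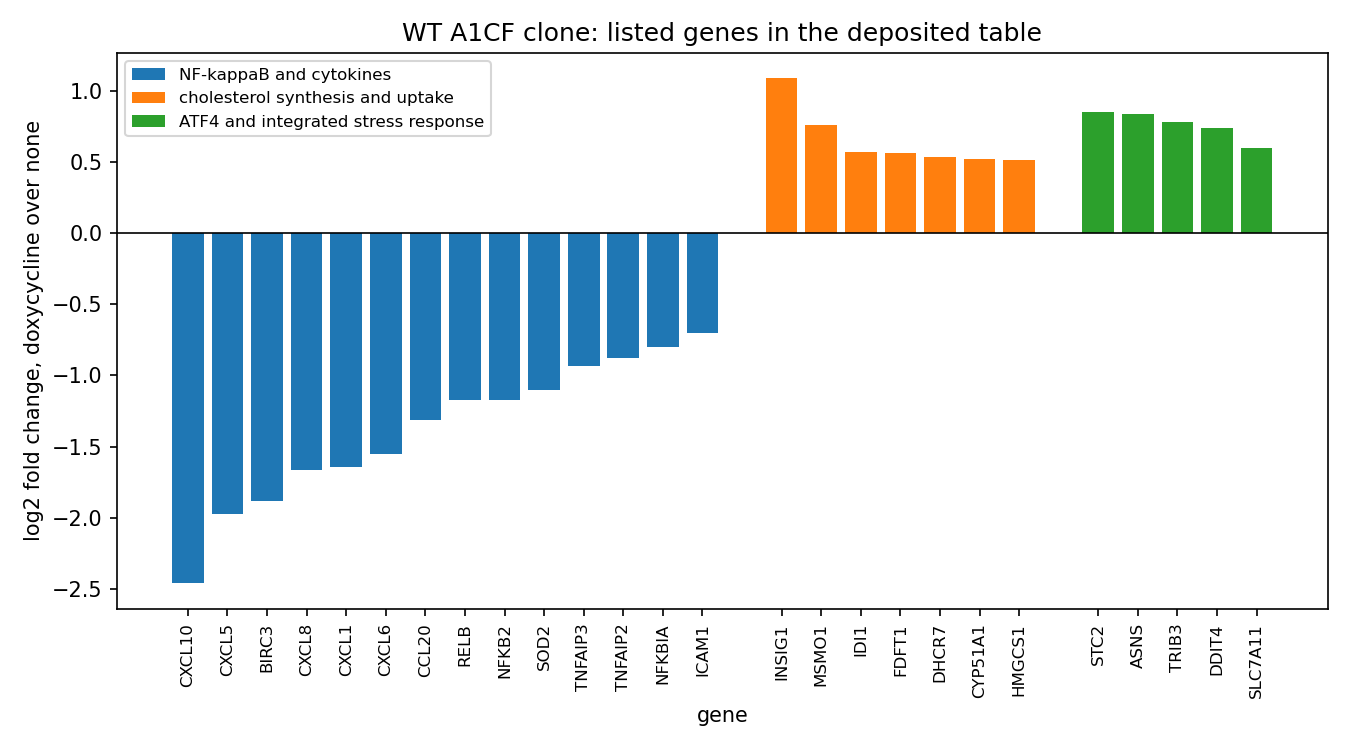
Log2 fold change with doxycycline over none in the WT clone (vertical axis) for each gene (horizontal axis) of 3 lists in the authors' deposited table. Each bar is 1 gene and starts at 0, without error bars because the table has no replicate values. The 14 NF-kappaB and cytokine genes lie below 0, and the cholesterol genes drawn and the 5 ATF4 genes lie above it.

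Outside the lists, the largest WT rise was that of MIR7845, a small RNA symbol chosen after its values were seen, from 0.794 to 10.5 FPKM. Its row spans chromosome 2 from 207938862 to 208033960, far more than a small RNA, so the symbol may not name the transcript measured. Among genes that the naming rule allows, the largest rise belonged to the alpha-globin gene HBA2, from 1.15 to 9.67 FPKM (implied standard error 2.15 on the log2 scale), and the largest falls to the fetal globin genes HBG1 and HBG2 (chromosome 11). HBG1 fell from 23802 to 186 FPKM and HBG2 from 13402 to 141 FPKM. These paralogs are nearly identical, and the library kit was designed to deplete globin RNA. With pooled values, a globin source in a single library, uneven depletion or carry-over from another sample could not be checked. Smaller rises named by the rule were SLC25A18, a mitochondrial carrier, NCR3LG1, BHLHE40, WASF3, PCDH9 and PDP2. In the authors' deposited table their log2 fold changes were 1.38, 1.21, 1.02, 0.97, 0.94 and 0.86, and those of SLC25A18, NCR3LG1 and WASF3 shrank to 0.66, 0.71 and 0.59 with 1 FPKM added. RNVU1-19, a variant U1 small nuclear RNA gene, fell 5.09-fold.

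Induction of G398S A1CF was accompanied by changes in many genes, most with modest folds. Of the list members in the table, genes of fatty acid and triglyceride synthesis rose (6 of 6) and most acute-phase genes rose (8 of 10), among them haptoglobin, HP, which was 4.44-fold higher. Histone (0 of 10 higher), replication and cell cycle (0 of 7), ribosomal protein (0 of 6), immediate early (0 of 5) and apolipoprotein genes (0 of 4) fell. Of these, the direction of the histone list alone differed from that of the other genes of the table after adjustment. Large rises included those of GSTA1, a glutathione transferase, ELOVL3, a fatty acid elongase, TGM3, a transglutaminase, and the globin genes.

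The G398S comparison comprised 1863 genes, 863 higher and 1000 lower. The median absolute log2 fold change was 0.49. At an absolute log2 fold change of at least 1, 164 genes were higher and 70 lower, so rises made up 70.1% of the larger changes against 46.3% of all.

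GSTA1 rose from 0.284 to 12.1 FPKM and ELOVL3 from 0.766 to 25.4 FPKM, giving log2 fold changes of 5.42 and 5.05 in the authors' deposited table (both q = 0.00104). TGM3 rose from 0.0742 to 2.38 FPKM and CASP1, the inflammatory caspase, from 0.0735 to 1.31 FPKM. Uninduced values this low inflate the ratios, and with 1 FPKM added to both groups the log2 fold changes were 3.36 for GSTA1, 3.90 for ELOVL3, 1.65 for TGM3 and 1.11 for CASP1. SLPI, a secreted protease inhibitor, was 13.3-fold higher and SLC27A2, a fatty acid transporter and acyl-CoA synthetase, 12.5-fold higher. HBB rose from 90.7 to 2896 FPKM, HBA2 from 87.3 to 1453 FPKM, HBG1 from 2.91 to 98.7 FPKM and HBG2 from 2.05 to 87.3 FPKM. Among genes that the naming rule allows, the largest fall was that of GBAS, from 31.6 to 5.89 FPKM, with a log2 fold change of -2.43 in the authors' deposited table. The lipid droplet gene CIDEC fell 3.47-fold, though from 1.13 FPKM, and the Wnt antagonist DKK1 fell from 144 to 51.7 FPKM. UBD fell from 25.4 to 7.95 FPKM and the efflux transporter ABCG2 from 3.30 to 1.22 FPKM. CGA, PHLDA2, TESC, ADA and LFNG completed the 10 largest falls allowed by the rule, with log2 fold changes of -1.71, -1.61, -1.45, -1.37 and -1.36 in the authors' deposited table. With 1 FPKM added these 5 were -1.04, -0.63, -0.82, -0.76 and -0.88, and CIDEC and ABCG2 were at -0.68 and -0.95.

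For fatty acid and triglyceride synthesis, ACSL1 rose from 7.90 to 15.7 FPKM, AGPAT2 from 71.6 to 109 FPKM, GPAM from 7.10 to 10.8 FPKM and LPIN1 from 3.04 to 4.43 FPKM, with ACSS2 and ELOVL5 also higher. Neither direction (Fisher exact test, adjusted p = 0.0529) nor number (adjusted p = 0.129) passed the threshold. The lipid droplet list had 8 genes against 2.18 expected (Fisher exact test, adjusted p = 0.00618), 4 higher and 4 lower, a number not called at a log2 fold change of at least 1 (adjusted p = 0.933). Among them FABP1, the liver fatty acid binding protein, fell from 76.2 to 49.1 FPKM, HILPDA fell 1.43-fold and the lipase cofactor ABHD5 rose 1.35-fold. The fatty acid oxidation list also had 8 genes (2.73 expected, Fisher exact adjusted p = 0.0226), again 4 each way, a number not called with at least 1 FPKM in the higher group (adjusted p = 0.323) or at a log2 fold change of at least 1 (adjusted p = 0.0679). EHHADH, a peroxisomal enzyme, rose 1.38-fold, while ANGPTL4 and ETFB fell 1.67-fold and 1.40-fold. With 1 FPKM added the log2 fold change of ANGPTL4 shrank from -0.74 to -0.43. In the apolipoprotein list APOA2 fell from 441 to 270.2 FPKM, APOE from 753 to 488 FPKM, APOA1 from 185 to 130.2 FPKM and MTTP, which loads lipid onto lipoproteins, from 112 to 74.3 FPKM. Neither the number (Fisher exact test, adjusted p = 0.569) nor the direction (adjusted p = 0.289) of that list passed the threshold. The cholesterol list had 4 genes higher, among them MSMO1, HMGCS1 and SC5D, and 1 lower (Fisher exact test, adjusted p = 0.368 for number and 0.392 for direction).

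The acute phase and complement list held 10 genes (4.04 expected, adjusted p = 0.0248), of which 8 rose (Fisher exact test, adjusted p = 0.175 for direction). Their number was not called with at least 1 FPKM in the higher group (Fisher exact test, adjusted p = 0.113) or without small RNA and several-gene rows (adjusted p = 0.0535). HP went from 5.76 to 25.6 FPKM, ORM1 from 35.8 to 96.4 FPKM and ORM2 from 13.6 to 33.3 FPKM, and F13B was 2.01-fold higher. The log2 fold change of F13B shrank from 1.01 to 0.61 with 1 FPKM added. ORM1 and ORM2 are close paralogs, so reads may be split between them. In the hepatocyte list CPS1 rose from 0.591 to 1.71 FPKM and RBP4 from 140.5 to 206 FPKM, and 6 genes fell, among them ASGR1 and FOXA3 (Fisher exact test, adjusted p = 0.0465 for number and 0.474 for direction). That number was not called at a q of 0.01 (Fisher exact test, adjusted p = 0.140) or with at least 1 FPKM (adjusted p = 0.113). Of the antioxidant and metallothionein list, HMOX1 and AKR1C2 rose 2.39-fold and 2.14-fold, whereas MT1A and MT1G, metal-binding metallothioneins, fell 2.12-fold and 2.09-fold. That list had 9 genes against 2.51 expected (Fisher exact test, adjusted p = 0.00408), 3 higher and 6 lower. The ATF4 list was split, with VLDLR, CEBPB and PSAT1 higher and GDF15 lower (5 higher and 4 lower, Fisher exact adjusted p = 0.0139 for number and 0.909 for direction). The NF-kappaB list was also split, 5 higher and 6 lower among 11 genes (Fisher exact test, adjusted p = 0.000597 for number and 1 for direction). At a log2 fold change of at least 1 the numbers of hepatocyte, ATF4 and NF-kappaB genes were not called (Fisher exact test, adjusted p = 0.937 for each). CXCL2 and TNFAIP3 rose 1.75-fold and 1.71-fold, and NFKB2 and RELB fell 1.61-fold and 1.57-fold. The log2 fold change of TNFAIP3 shrank from 0.77 to 0.40 with 1 FPKM added.

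Histone genes fell together (10 genes against 2.84 expected, Fisher exact adjusted p = 0.00277 for number and 0.0215 for direction), though none of the 10 changed by a log2 of 1 or more. HIST2H2AC went from 1071 to 754 FPKM, HIST1H2BH from 704 to 515 FPKM, HIST1H3B from 2941 to 2197 FPKM and HIST1H4B from 2645 to 1985 FPKM. With directions shuffled among genes of similar transcript length, the histone direction was no longer called (permutation test, adjusted p = 0.204), their median annotated transcript being 829.5 nucleotides long. In the proliferation list CENPE, CCND1, MCM5 and MCM3 fell 1.45-fold, 1.44-fold, 1.36-fold and 1.34-fold, and MCM2, E2F1 and PCNA fell as well (Fisher exact test, adjusted p = 0.0775 for direction). RPS12, RPL13 and RPLP0 led the ribosomal proteins, with log2 fold changes from -0.39 to -0.34 in the authors' deposited table (Fisher exact test, adjusted p = 0.129 for direction). DUSP5 and SPRY2, inhibitors of growth factor signalling, fell 2.40-fold and 1.83-fold in the immediate early list (Fisher exact test, adjusted p = 0.197 for direction).

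The remaining lists passed neither test. RBM47, a partner of A1CF in editing, rose from 4.71 to 6.16 FPKM and BAG4 from 12.6 to 18.7 FPKM, with 3 of 3 genes of the editing list higher (Fisher exact test, adjusted p = 0.250 for direction). PTBP2 and SRSF5 of the splicing list rose 1.66-fold and 1.23-fold. In the interferon list 5 of 6 genes rose, among them IFIT1, IRF1 and IFIT5 (Fisher exact test, adjusted p = 0.250 for direction). HSPA5, HERPUD1 and EDEM1 of the unfolded protein list rose and SDF2L1 fell. The glycolysis list had 3 genes higher, among them HK2 and EGLN3, and 4 lower, among them SLC2A1. SPP1, SOX9 and KRT19 of the cholangiocyte list fell 2.16-fold, 1.59-fold and 1.49-fold. SLC51B, a bile acid transporter subunit, rose 2.19-fold, PCK2 fell 1.41-fold, LYZ fell 1.88-fold and ESAM fell 2.19-fold. With 1 FPKM added the log2 fold change of ESAM shrank from -1.13 to -0.57 and that of SOX9 from -0.67 to -0.33. The matrix list had 2 genes higher and 4 lower, the latter including TAGLN, MMP14 and THBS1. The p53 list had 3 genes lower, AEN, PLK2 and GDF15, and 2 higher, among them TP53INP1. The respiratory chain list had 1 gene and the mitochondrially encoded list had none.

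The direction of change in the G398S clone went with the base composition of the transcripts. Genes that rose had a median GC content of 43.6% and genes that fell 54.9% (higher minus lower, -11.2 percentage points, permutation test, p = 1e-05, the smallest these permutations can give). Genes that fell also had shorter annotated transcripts, with a median of 3200 against 4290 nucleotides (permutation test, p = 1e-05, again the smallest possible). In the WT clone the medians were 44.9% for rises and 49.6% for falls (permutation test, p = 0.0094), and 4600.5 against 2597 nucleotides (p = 1e-05). By chromosome, 18 of 103 G398S genes on chromosome 19 rose (17.5%), against 17 of 22 on chromosome 13 (77.3%). The median GC content of apolipoprotein, histone and fatty acid synthesis genes in the G398S table was 58.4%, 51.1% and 46.3%. With directions shuffled within GC deciles, the histone list kept its call and the fatty acid list gained 1 (permutation test, adjusted p = 0.0236 for both). Within transcript length strata neither was called (permutation test, adjusted p = 0.204 and 0.0554).

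**Figure D2:**
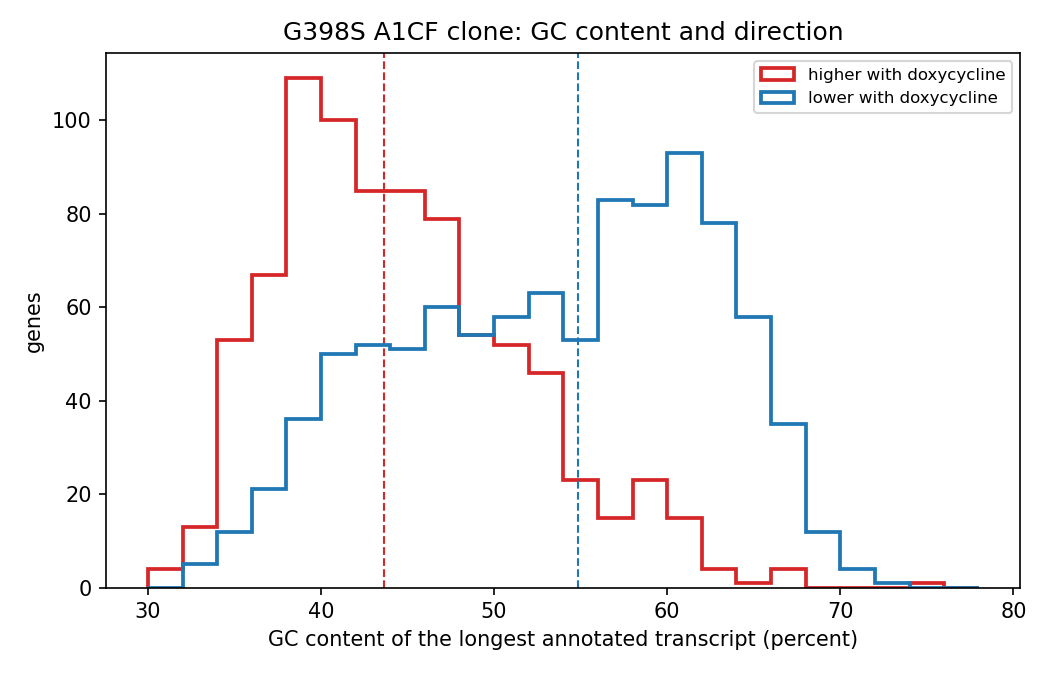
Number of G398S genes (vertical axis) by GC content of the longest annotated transcript in percent (horizontal axis), for genes higher and genes lower with doxycycline. Dashed lines mark the medians, 43.6% for genes that rose and 54.9% for genes that fell.

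The 2 inductions shared 65 genes, 45.8% of the WT genes, against 15.5 expected from independent lists (exact hypergeometric test, p = 5.00e-26). Of these, 22 rose in both, 24 fell in both, 4 rose in WT and fell in G398S, and 15 fell in WT and rose in G398S. Signs matched for 70.8% (95% exact binomial interval 58.2% to 81.4%, p = 0.00109), but the match was no longer past the threshold among shared genes with a q under 0.01 (66.7%) or a log2 fold change of at least 1 (60% of 10 genes). The clones have separate controls, so the overlap is not raised by shared libraries. The expected number takes every tested gene as equally likely to be called, however. Genes with higher values are easier to call in either clone, which can raise the overlap, so the number shared does not by itself show a shared response. UBD fell in both, with log2 fold changes of -2.22 and -1.68 in the authors' deposited tables, and HBA2 rose in both. MSMO1, TRIB3 and DDIT4 were among the genes that rose in both, and LYZ, MMP14, RELB and NFKB2 among those that fell in both.

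The difference between the inductions was called for 21 of the 65 genes, which included all 19 with opposite signs as well as A1CF and CXCL8. A gene called in both tables with opposite signs was nearly sure to pass this test. Of the 15 genes that fell with WT and rose with G398S, all but CXCL1 had higher uninduced FPKM in the WT clone. STC2, ASNS and ONECUT2, which went the other way, also started higher there, and FAT4 did not. With 1 clone per construct, an effect of the construct cannot be told apart from these starting levels. SLPI fell from 196 to 130 FPKM with WT and rose from 2.40 to 32.0 FPKM with G398S. PI3, another protease inhibitor, fell from 125 to 67.3 FPKM with WT and rose from 5.98 to 18.0 FPKM with G398S. The chemokine gene CCL20 fell from 367 to 148 FPKM with WT and rose from 88.8 to 139 FPKM with G398S, and CXCL5 rose there from 13.3 to 17.5 FPKM. ACSL1 fell from 21.1 to 14.1 FPKM with WT and rose with G398S, while STC2 and ASNS rose with WT and fell with G398S. As a list, NF-kappaB and cytokine genes differed in direction between the tables, 0 of 14 higher with WT and 5 of 11 with G398S (Fisher exact test, adjusted p = 0.0435 over 5 lists). That test counts the 9 list genes in both tables as if they were separate genes, so its p-value is approximate. Those 9 all fell with WT, while 4 rose and 5 fell with G398S. The acute phase list, 0 of 3 higher with WT and 8 of 10 with G398S, did not pass (Fisher exact test, adjusted p = 0.0874) except at a log2 fold change of at least 0.5 (adjusted p = 0.0364), nor did the cholesterol, fatty acid and ATF4 lists (adjusted p = 0.385, 0.385 and 0.368). The standard error implied for a shared gene was larger in the WT table by a median factor of 1.38, and the smallest absolute log2 fold change in it was 0.49. With the G398S statistics rescaled by that ratio, 440 G398S genes remained at or above the 5th percentile of the WT statistics, 3.10 times the 142 WT genes, and 940 exceeded the smallest WT change. Standard errors are implied for listed genes alone, so these counts are approximate. Rescaling leaves the link between direction and GC content in the G398S table in place. A library difference behind part of the G398S calls could not be checked.

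**Figure D3:**
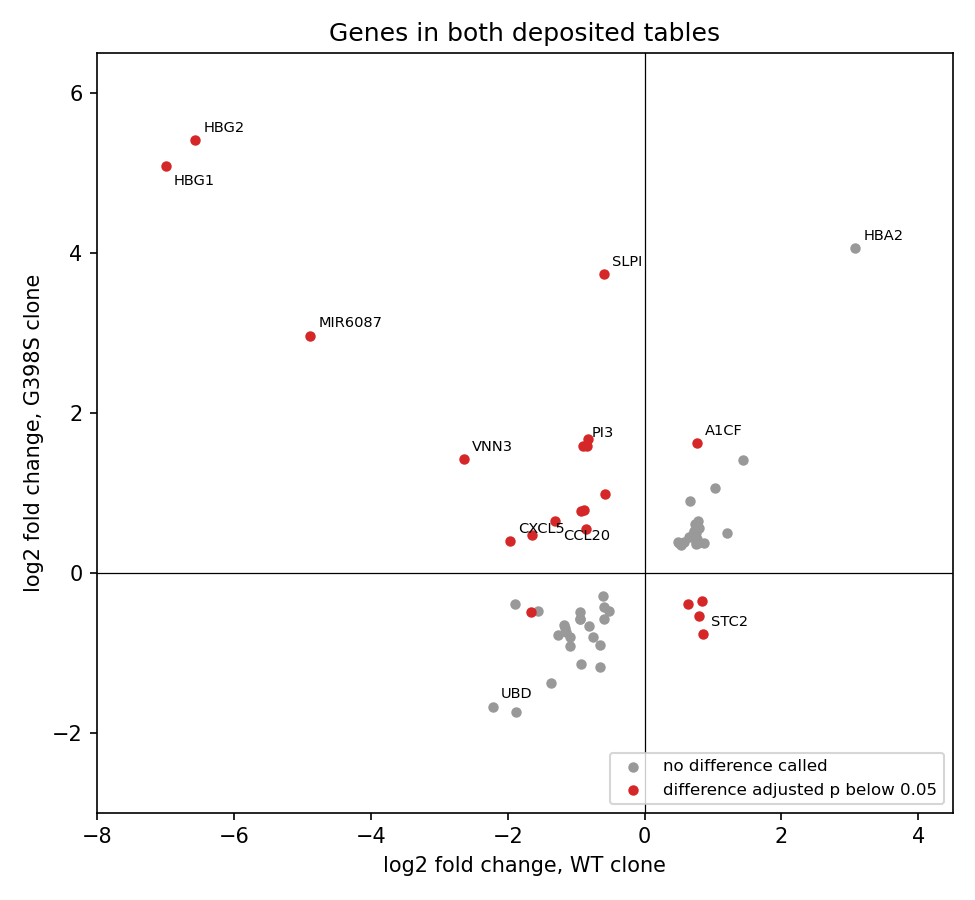
Log2 fold change with doxycycline in the WT clone (horizontal axis) and the G398S clone (vertical axis) for the 65 genes in both of the authors' deposited tables, 1 point per gene. Red points are the 21 genes whose 2 log2 fold changes differed past the adjusted threshold of 0.05, and HBG1 and HBG2 lie farthest from the rest.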

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

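The tests of globin proportions, of doxycycline acting alike, of clone differences, of a stronger induction, of pairs 10 to 100 kb apart and of neighbouring genes as such were chosen after the values were seen. So were the tests of lists between tables and the use of the difference test although its condition was not met. The others in this part were set out first.

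Inductions of the 2 clones differed, G398S minus WT on the log2 scale, by 11.98 for HBG2 and 12.08 for HBG1. SLPI differed by 4.34, VNN3 by 4.07, MYH4 by 2.501 and PI3 by 2.49. MYH4 had low values. With 1 FPKM added its log2 fold changes shrank from -0.82 to -0.50 with WT and from 1.68 to 0.97 with G398S. Chemokine and NF-kappaB genes differed by 2.37 (CXCL5), 2.12 (CXCL1), 1.96 (CCL20), 1.70 (TNFAIP3) and 1.18 (CXCL8). ACSL1 differed by 1.57 and A1CF by 0.86, while the stress genes STC2 and ASNS differed the other way, by -1.62 and -1.19. Each of these passed the test of the difference itself over the 65 shared genes, which is approximate. A1CF did not pass with standard errors from the p-values. All of these genes but A1CF and CXCL8 had opposite signs, for which the test was nearly sure to pass. The NF-kappaB and cytokine list differed in direction between the tables (Fisher exact test, adjusted p = 0.0435). That test is also approximate, because it counts the 9 list genes in both tables as if they were separate.

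Globin genes were among the largest changes in both clones, though hepatoma cells are not a usual source of them and the kit depletes globin RNA. A single source of blood RNA with globin proportions fixed in the WT libraries, after depletion, is argued against, because HBA2 rose while HBG1 fell. Their log2 fold changes differed by 10.08, with implied standard errors of 2.15 and 0.69. HBA2 was low, at 1.15 FPKM without and 9.67 FPKM with doxycycline. Depletion that removed each globin to a different extent in each library could change these proportions and was not tested. In the G398S libraries HBA2, HBB, HBG1 and HBG2 rose together with log2 fold changes spanning 1.35, which such a source could give, as could carry-over from another sample, which pooled values cannot test. Of 47 other erythroid genes listed for the test, 1 was higher (BPGM) and 2 were lower (BLVRB and TAL1), a balance of -1. That balance met the bound set for excluding whole erythroid cells, but the bound was wrong, since BLVRB at 82.2 FPKM and BPGM at 19.2 FPKM without doxycycline would hide a small share and TAL1 was near the floor.

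The fall of the NF-kappaB and cytokine list with WT A1CF was set against technical and biological readings. Globin reads displacing others in the uninduced WT libraries would shift other genes by 0.0404 on the log2 scale, far below the list median of -1.24. Doxycycline changing both clones by the same log2 amount is argued against for 5 of the 9 list genes in both tables, whose changes differed. For 4 of the 5 the evidence is the opposite signs themselves, since the difference test was then nearly sure to pass. A stronger A1CF induction with the same effect is argued against by these 4, which rose with G398S and differed. A difference between the clones before induction cannot be told apart from the construct, since each construct had 1 clone, and uninduced levels of the 9 genes differed by a median of 0.68 on the log2 scale in either direction. Of the 4 that rose with G398S, all but CXCL1 started higher in the WT clone. A different effect of the 2 A1CF forms stays open as a biological reading. An effect of doxycycline that depends on the clone or its starting levels stays open too. RELB, NFKB2 and BIRC3 fell in both clones with no difference called, so a common effect of doxycycline stays open for them. These readings are untested because no second clone or doxycycline control was analysed.

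Neighbouring genes of the G398S table tended to change in the same direction, with 79.1% of 373 consecutive pairs under 100 kb apart sharing a sign. The mean was 50.3 ± 2.58% (SD over 10000 shuffles of direction, p = 0.0001, the smallest these permutations can give). GC content as the whole cause is argued against, because the observed share exceeded that shuffled within GC deciles by 16.9 percentage points, although the deciles alone raised the mean to 62.2%. Transcript length left an excess of 27.4 percentage points, and pairs 10 to 100 kb apart, which do not overlap, an excess of 26.3, or 15.1 within GC deciles. Families of related genes were not left out of the pairs and may add to these shares. A library difference in base composition may still account for part of the pattern, and local regulation of neighbouring genes is a hypothesis that the same pairs prompted.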

How the results depend on the processing

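The alternatives with globin rows left out, with directions shuffled within strata, with other matching, with the tests between tables, with the number of genes tested scaled by the share analysed, and the difference test itself were chosen after the data were seen; the others were planned. No paired analysis was possible because each table holds 1 value per group, and for the same reason leaving out each replicate, the replicate block and other splits of the libraries were not run. Depth per library is unknown, and q-values of single genes rest on the authors' test. At a q of 0.01 there were 91 WT genes, 1122 G398S genes and 36 shared genes, of which 66.7% had the same sign. At an absolute log2 fold change of at least 1 there were 51, 234 and 10 genes, and 60% of the 10 had the same sign. That setting called 0 list directions against 3 and 3 list enrichments against 13, and no ATF4 gene of WT or histone gene of G398S was left (Fisher exact test, adjusted p = 1 for both), because few list genes change that much. The 3 enrichments kept were NF-kappaB genes of WT and acute phase and antioxidant genes of G398S. Besides the 2 lists above, those lost were cholesterol, fatty acid synthesis and acute phase genes of WT and lipid droplet, fatty acid oxidation, hepatocyte, ATF4 and NF-kappaB genes of G398S (Fisher exact tests, adjusted p from 0.0679 to 0.937). List directions called numbered 5 with at least 1 FPKM, 5 without small RNA and several-gene rows and 5 within GC strata; the cause was not tested. Within GC strata the gains were ATF4 genes of WT (permutation test, adjusted p = 0.0243) and fatty acid genes of G398S (adjusted p = 0.0236), neither of which was called within length strata (adjusted p = 0.0632 and 0.0554). Within transcript length strata 3 directions were called, losing histones (permutation test, adjusted p = 0.204) and gaining acute phase genes of G398S (adjusted p = 0.0369). The histone direction was also lost at a q of 0.01 (Fisher exact test, adjusted p = 0.103). The NF-kappaB direction in WT kept its call except at the log2 minimum (Fisher exact test, adjusted p = 0.285), the cholesterol direction kept its call in every setting that left at least 3 of its genes, and the difference of the NF-kappaB list between tables had adjusted p from 0.0296 to 0.0435. At a log2 fold change of at least 0.5, 2 lists differed between tables against 1, the second being acute phase genes (Fisher exact test, adjusted p = 0.0364). The number of list genes in a table lost its call for G398S acute phase, hepatocyte and fatty acid oxidation genes with at least 1 FPKM. It was also lost for G398S acute phase genes without small RNA and several-gene rows, and for WT acute phase and G398S hepatocyte genes at a q of 0.01. Rescaling the G398S statistics by the median ratio of standard errors, added after the data were seen, left 440 genes. The number tested in WT gave 17.5 genes expected to be shared, and that number scaled by the share analysed gave 21.2. With a standard error from the p-value, 22 genes differed between inductions, 20 of them in both versions; A1CF was lost and BEND3 and CXCL6 were gained. Shuffling G398S directions within GC deciles gave 34.9 ± 3.59 genes of the same sign (SD over shuffles) against 46 observed (permutation test, p = 0.0007). Pseudocounts turned no named gene, but a pseudocount of 1 FPKM moved 30 of 159 log2 fold changes toward 0 by at least the standard error implied for the gene, and 0.1 FPKM moved 1. That error is large for genes with low values, so CASP1, at 4.16 in the authors' deposited table, does not count as moved at 1.11. With 1 FPKM added, 31 log2 fold changes shrank by more than 1.5 times.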

Other observations

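The tests and values in this part were chosen after the data were seen. Uninduced levels of several epithelial and immune genes were far apart between the clones, in tables normalised separately. TRIM31 was at 45.7 FPKM in the WT clone and 0.182 FPKM in the G398S clone, SLPI at 196 and 2.40 FPKM, PI3 at 125 and 5.98 FPKM, CTSE at 25.0 and 1.13 FPKM, and LYZ at 83.9 and 7.29 FPKM. With doxycycline, TRIM31 fell to 25.4 FPKM in the WT clone and rose to 0.544 FPKM in the G398S clone. These differences between clones were not tested.

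Of 44 genes with the same sign in both tables, A1CF and globin left out, 7 changed more in the G398S clone (exact binomial test, p = 5.30e-06), with median absolute log2 fold changes of 0.78 in WT and 0.57 in G398S. The WT table needed larger changes for a gene to be listed, the smallest being 0.49 against 0.29, which favours this outcome. Some responses were close in both clones. BHLHE40, a transcription factor, had log2 fold changes of 1.02 and 1.05 in the authors' deposited tables, MMP14 of -0.59 and -0.58, SGK1 of -0.51 and -0.48, and the long noncoding RNA MALAT1 of 0.49 and 0.39. The intervals of the differences still allow gaps of -0.75 to 0.81 for BHLHE40 and -0.62 to 0.64 for MMP14. Doxycycline was common to both, and no cells without a construct were analysed. MIR6087 fell from 247 to 8.31 FPKM with WT and rose from 0.782 to 6.11 FPKM with G398S. HBG1 and HBG2 changed in the same directions. The symbol MIR6087 is that of a small RNA, but its WT row spans chromosome X from 108297334 to 108297874. The RNA measured is therefore not settled.

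Neighbouring G398S genes with large changes of the same sign included THEMIS2 and SMPDL3B on chromosome 1 (log2 fold changes of 2.73 and 2.82 in the authors' deposited table), TLR5 and SUSD4 on chromosome 1 (1.98 and 1.55), and CDKN1C and PHLDA2, imprinted genes on chromosome 11 (-1.18 and -1.61). Other such pairs were related genes, among them MT1A and MT1G (-1.08 and -1.06), HP and HPR (2.15 and 1.07), and ORM1 and ORM2 (1.43 and 1.29). At 1 to 10 Mb apart the share of pairs with the same sign was 55.3%, against a shuffled mean of 50.3% (permutation test, p = 0.0041). Local regulation is a candidate explanation for the share of 79.1% under 100 kb, and the decline with distance is what it would give, but regional base composition could give it too.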
